A study of Mus musculus with 9 samples.

How the data were processed

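Poly(A) RNA libraries were made from kidneys of 9 mice on a C57BL/6 background, 3 wild type, 3 with Pkd2 knocked out and 3 with Pkd2 and Ift88 knocked out together. Per the labels, the mutants carry floxed alleles with Pax8-rtTA and TetO-cre, so that doxycycline turns on the deletion. Per the labels' protocols, all mice drank doxycycline at 2 mg/ml for 2 weeks from postnatal day 28, and kidneys were taken at 10 weeks (postnatal day 70) and extracted with Trizol. Groups and replicate numbers were taken from the sample labels, and the series design states that the replicates are biological. The mouse names carry different prefixes: replicates 1 and 2 of the wild type group share one and replicate 3 has another, the same holds for the Pkd2 knockout group, and the 3 mice with both genes knocked out share a prefix of their own, which one of them writes with a hyphen. No prefix occurs in more than 1 group, so the prefix cannot be separated from genotype.

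The deposited table holds normalized counts per gene, a signal made by the authors from reads aligned with STAR 2.5.0, counted with HTSeq 0.6.1 and scaled with DESeq2, per the submitters' processing notes. The genome build, annotation and DESeq2 version are not given in the sources used here, nor whether the counting used strand, so overlapping and antisense genes cannot be told apart from their partners. The table has 22161 gene rows, none of them listed at 0 in all samples, and 25 row names had been turned into dates and name no gene that is discussed. Normalized totals ranged from 40454151 to 42874467 per library. Dividing each column by the value of 1 read (0.906 to 1.13) gave whole numbers for 100% of values at a tolerance of 0.05. For 7 libraries this recovered 37056843 to 47314829 reads each. In WT replicate 1 and Pkd2 knockout replicate 1 the value of 1 read lies too near to 1 to separate a scaled from an unscaled count, so these 2 libraries entered no count test and their read totals are not given. Because poly(A) reads without molecular identifiers are not independent molecules, counting intervals would understate the error, and the errors given are standard deviations or standard errors between mice.

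The 3 groups were compared in one limma model (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), with one mean per group, an intensity trend and no block, over the 15740 genes with a mean of at least 10 in the 9 libraries. The fit takes the mice of a group as independent. If mice that share a name prefix are related, its p-values are too small. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Log2 fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. The design, the alternatives other than those set apart below and 43 gene lists (763 distinct members, of which 5 are not in the table) were fixed before the data were examined. List members count as higher or lower only if they pass over all genes tested. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists. Some lists share members, so their tests are not independent. A list score per mouse is the mean over members of the log2 difference from the wild type mean.

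The named genes follow a rule fixed in the same way: Pkd2, Ift88 and Pkd1; up to 8 largest rises and up to 8 largest falls among called genes whose groups do not overlap and whose mean is at least 50, without clone names or pseudogenes; up to 4 called members of each list that camera called or of which enough members were called; sex-linked genes; and, as an uncalled example, a list's most abundant uncalled member. Genes named outside this rule are said to be so. The uncalled example of 1 list is not reported here.

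Comparisons that share libraries were set beside 100 simulated draws of unchanged groups. Other alternatives were pseudocounts of 0.1 and 10, no filter and a mean of at least 50, median-ratio, quantile and TMM scaling, no intensity trend, array quality weights, only the groups compared, a replicate block, a log2 fold of at least 1, leaving out each library, and edgeR 4.0.16 and DESeq2 1.42.0 on the 7 libraries with recovered reads. A fit of limma to the same 7 libraries and a fit without WT replicate 3 and Pkd2 knockout replicate 3 were chosen after seeing the data. Leaving out each library was planned for the counts of called genes but not for the list tests. Chromosomes were taken from GENCODE M21, which may not be the authors' annotation; 94.1% of tested genes matched it by symbol, and no coordinates are given. The linkage tests used 10000 circular shifts of the calls along the gene order.

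The procedure was tested on simulated data drawn from the real means, the spreads estimated by limma and the normalized totals. Changes were placed only in genes with a mean of at least 50, and the mice were drawn as independent. The noise has the form that limma assumes, which may not suit the other tools. For Pkd2 knockout against wild type, over 15679 genes, limma recovered 83% of 100 genes changed 2-fold and 97% of 100 changed 4-fold, with 9 false calls among 189. DESeq2 on 7 libraries made 77 false calls among 259 in the same simulated comparison, and edgeR 10 among 176. Further calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.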

Results

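The series profiled kidney RNA from 10-week-old mice in which Pkd2 was knocked out alone or together with Ift88. Pkd2 encodes the cation channel polycystin-2 and is mutated in autosomal dominant polycystic kidney disease, and Ift88 encodes an intraflagellar transport protein needed to build cilia. Per the genotype labels, floxed alleles were removed by a cre that doxycycline switches on through Pax8-rtTA, a driver active in kidney tubules. Each of the 3 groups (wild type, Pkd2 knockout, and double knockout of Pkd2 and Ift88) held 3 mice, and WT, KO and DKO followed by a number denote one mouse of each group. Normalized totals lay between 40454151 and 42874467 per library, and mitochondrially encoded genes took 9.21 to 10.8% of them. All 9 mice had the pattern of males, with Xist between 4.35 and 20.4 normalized counts and Ddx3y between 3130 and 4170.

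Pkd2 fell in both mutant groups. It was 14095 ± 375 normalized counts in wild type, 5118 ± 414 in Pkd2 knockout and 4687 ± 789 in double knockout kidneys (SD, n = 3), which is 36.3% and 33.3% of wild type. Both falls passed limma's test (log2 fold changes of -1.46 ± 0.12 and -1.60 ± 0.12, SE; adjusted p of 0.000972 and 0.000843). The first missed the threshold with edgeR on 7 libraries (adjusted p = 0.0581). Ift88 was 1085 ± 41.0 in wild type, 1140 ± 66.0 in Pkd2 knockout and 752 ± 71.4 in double knockout kidneys. Its fall against Pkd2 knockout passed (log2 fold change of -0.60 ± 0.09, adjusted p = 0.0358), and the difference from wild type did not (-0.53 ± 0.09, adjusted p = 0.0617). The Ift88 call against Pkd2 knockout was lost without WT 1 (adjusted p = 0.0642), WT 2 (0.0687), KO 1 (0.121), KO 2 (0.126), DKO 1 (0.109) or DKO 2 (0.117). It was also lost with edgeR (0.189) and with only these 2 groups in the fit (0.0984). Against wild type Ift88 passed without DKO 3 (0.0449) and with array quality weights (0.00913). Pkd1, which encodes the partner protein polycystin-1, did not pass in any comparison (2239 ± 248, 2575 ± 260 and 2554 ± 227). Reads outside a deleted exon are still counted, so the level of a deleted gene's transcript is not the share of cells that kept it.

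**Figure D1:**
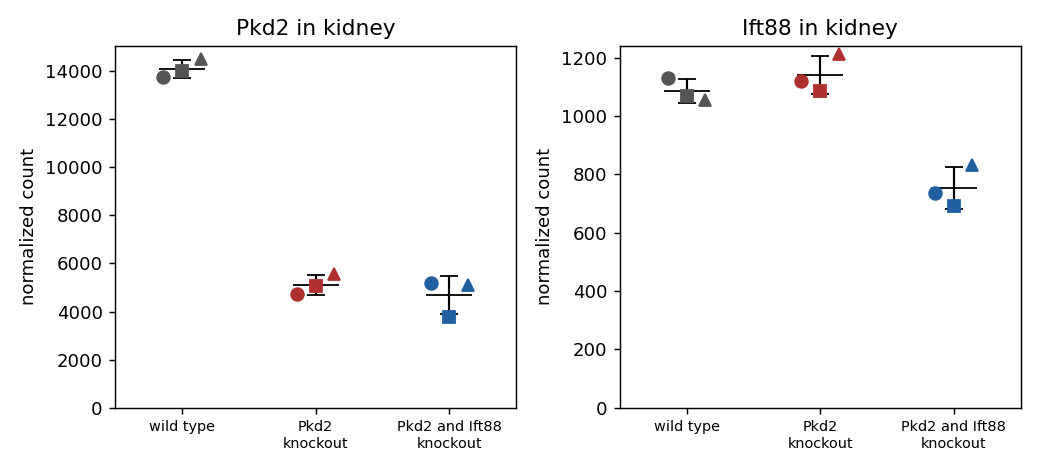
Normalized counts of Pkd2 (left) and Ift88 (right) on the vertical axes for each mouse of the 3 groups; symbols mark replicates 1 (circle), 2 (square) and 3 (triangle), and lines show the mean and SD. Pkd2 lies at 36.3% of wild type in Pkd2 knockout and 33.3% in double knockout kidneys, and Ift88 is lowest in the double knockout.

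The first comparison asked what loss of Pkd2 changed. Genes of mitosis rose together: of 25 measured members of the G2/M list, 20 rose, none fell and 5 did not pass, with a median log2 fold change of 2.05. Markers of the thick ascending limb, the salt-reabsorbing segment of the nephron, fell in 7 of 13 members and rose in none. Genes of cholesterol synthesis fell in 4 of 18 members. In all, limma called 377 of 15740 genes, 180 higher and 197 lower. The groups of all 377 did not overlap, as was the case for 25.2% of tested genes, against 10% by chance. The call count was 106 without WT 1, 70 without WT 2, 91 without KO 1 and 80 without KO 2. edgeR on the 7 libraries with recovered reads called 11 genes, 2 higher and 9 lower, and limma on those same 7 libraries called 13, 3 higher and 10 lower. Array quality weights gave 3222, and a log2 fold of at least 1 left 161, of which 99 were higher and 62 lower. Of all listed genes, edgeR called 1, in the G2/M list. Of 41 genes that the naming rule took from the calls of this comparison, 15 stayed called without any 1 library and 26 did not, and the latter are identified in the paragraph that names them.

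Ccnb2, which encodes cyclin B2, went from 25.7 ± 8.19 to 178 ± 27.4 normalized counts, a log2 fold change of 2.77 ± 0.26 (SE, adjusted p = 0.00242, limma). Mki67, the proliferation marker Ki-67, rose from 166 ± 31.0 to 1104 ± 117, by 2.73 ± 0.30 on the log2 scale. Top2a, a topoisomerase of dividing cells, and Cdk1, the kinase that drives entry into mitosis, rose by 2.43 ± 0.25 and 2.51 ± 0.26. Ccna2, encoding cyclin A2, rose by 2.05 ± 0.20. Cenpf, a kinetochore protein, Hmmr and Tpx2, both of the spindle, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by 2.85, 2.75, 2.55 and 2.62. Ckap2, a spindle-associated protein, rose by 2.61 and the anoctamin Ano3 by 2.70. Nusap1, the most abundant G2/M member that did not pass, was 158 ± 76.4 in wild type and 284 ± 56.2 in Pkd2 knockout. Adjusted over the list alone, 24 of the 25 members rose, and camera placed the list above other genes (adjusted p = 9.77e-29; adjusted p = 0.115 with an estimated correlation). In the G1/S list, 2 of 20 members rose: Rrm2, a subunit of ribonucleotide reductase, by 1.42 ± 0.17 and Uhrf1, which maintains DNA methylation at replication, by 1.39 ± 0.24. Of the G1/S genes 9 rose adjusted over the list alone (camera adjusted p = 1.24e-07; adjusted p = 0.115 with an estimated correlation). The G2/M list had 11 members called without WT 2 or without KO 2, and 1 with edgeR or with limma on 7 libraries. Hmmr, Ckap2 and Tpx2 were not called without WT 2 or KO 2 (highest adjusted p of 0.0653). Uhrf1 was not called without WT 1, WT 2, KO 1 or KO 2 (highest 0.101), which left 1 G1/S member, and Ano3 was not called without any one WT or KO mouse or DKO 2 (highest 0.109).

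Markers of the distal nephron were lower. In the thick ascending limb list, Egf, which encodes epidermal growth factor, fell from 102380 ± 4307 to 47759 ± 2911 normalized counts (log2 fold change -1.10 ± 0.13, adjusted p = 0.00518). Slc12a1, the sodium-potassium-chloride cotransporter NKCC2, fell by 0.87 ± 0.12, Ptger3, a prostaglandin E receptor, by 0.61, and Ppp1r1a, a phosphatase inhibitor, by 0.83. Kcnj1, the potassium channel ROMK, was 9352 ± 1061 and 6596 ± 870 and did not pass (adjusted p = 0.0672). Of the 13 members 12 fell adjusted over the list alone, and camera gave an adjusted p of 4.36e-12 (adjusted p = 0.113 with an estimated correlation). In the distal convoluted and connecting tubule list 2 of 11 members fell, the calcium-handling genes Slc8a1 (-0.78 ± 0.11) and Calb1 (-0.82 ± 0.17), and 7 adjusted over the list alone. Its camera adjusted p was 7.24e-07 (adjusted p = 0.113 with an estimated correlation). Slc12a3, the thiazide-sensitive cotransporter, was 32692 ± 5429 and 23076 ± 122 and did not pass. Among markers of intercalated cells of the collecting duct, Atp6v1g3, a proton pump subunit, fell in kidney RNA by 0.58 ± 0.09 as the 1 called member of 12, and 6 fell adjusted over the list alone (camera adjusted p = 0.000667; adjusted p = 0.435 with an estimated correlation). Of 12 principal cell markers limma called 0, also adjusted over the list alone, with 2 lower at an unadjusted p under 0.05 and 0 by DESeq2 or edgeR (median log2 -0.29, camera adjusted p = 0.00206; adjusted p = 0.447 with an estimated correlation). The thick ascending limb count was 1 without WT 2, 2 without KO 1, 3 without KO 2 and 4 without WT 1. Slc12a1 was not called without WT 2 (adjusted p = 0.0542), Ptger3 without WT 2 or KO 1 and Ppp1r1a without WT 1, WT 2, KO 1 or KO 2 (highest 0.0788 for both). Atp6v1g3 was not called without WT 1, WT 2 or KO 1 (highest 0.0788), and its list had 2 called members without DKO 1 and 4 without DKO 3. Slc8a1 was not called without KO 1 (0.0507), nor was Calb1 without any one mouse other than DKO 2 (highest 0.135).

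Smaller numbers of metabolic genes fell. Of the cholesterol synthesis genes, Fdft1 (squalene synthase), Cyp51 (lanosterol demethylase), Insig1 (a sterol-regulated brake on the pathway) and Fdps (farnesyl diphosphate synthase) fell by 0.59, 0.96, 1.13 and 0.56 on the log2 scale. Of the 18 members 5 fell adjusted over the list alone (camera adjusted p = 0.000192; adjusted p = 0.115 with an estimated correlation). Hmgcs1, encoding a synthase early in the pathway, was 38360 ± 2804 and 37814 ± 4566. In glycolysis 3 of 20 members fell, Hk1 (hexokinase), Pfkm (phosphofructokinase) and Pkm (pyruvate kinase), by 0.46, 0.36 and 0.51. In this list 6 genes fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00227; adjusted p = 0.447 with an estimated correlation; 0.0990 without WT 3 and KO 3 together). Limma called 0 of 26 members of oxidative phosphorylation and the TCA cycle, also adjusted over the list alone, with 7 lower at an unadjusted p under 0.05 and 0 by DESeq2 or edgeR. All 26 had lower means (median log2 -0.16, camera adjusted p = 4.94e-06; adjusted p = 0.451 with an estimated correlation). Prodh2, hydroxyproline dehydrogenase, fell from 2234 ± 158 to 794 ± 158 as the 1 called of 24 gluconeogenesis and amino acid genes (median -0.14, camera adjusted p = 0.0184; adjusted p = 0.451 with an estimated correlation). That list was not called without WT 3, KO 1 or KO 2 (highest adjusted p of 0.103) or with quantile normalization (0.176), and it had 2 called members without KO 3. Of 26 xenobiotic genes, Abcc2, an organic anion exporter, rose by 0.63 ± 0.13, while adjusted over the list alone 2 rose and 5 fell (median -0.18, camera adjusted p = 0.0467; adjusted p = 0.447 with an estimated correlation). The xenobiotic call was lost without WT 1, WT 2, KO 1, KO 2 or DKO 2 (highest 0.191), with quantile normalization (0.182) and with a replicate block (0.0568). Abcc2 was not called without any one WT or KO mouse or DKO 2 (highest 0.105). That list had 2 members called lower without KO 3, and 1 higher and 1 lower without DKO 3. The cholesterol count was 0 without WT 1, WT 2, KO 1 or KO 2 and 1 without WT 3, and no glycolysis gene was called without any one WT or KO mouse or DKO 1 (highest adjusted p of 0.153 for Fdps and 0.146 for Hk1). Fdps was called only with all libraries or without DKO 3.

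Macrophage, complement, stromal and injury lists were higher by camera with 0 members called by limma. These lists are not independent. The macrophage and complement lists share C1q genes, and the fibroblast and matrix lists share collagen genes. Macrophage and monocyte genes had a median log2 fold change of 0.63 (camera adjusted p = 5.57e-05; adjusted p = 0.447 with an estimated correlation), and Csf1r, the receptor for macrophage colony-stimulating factor, was 3084 ± 126 and 3424 ± 130. Complement genes had a median of 0.54 (adjusted p = 0.389 with an estimated correlation), collagen and matrix genes 0.27 (0.451), tubular injury genes 0.22 (0.583), matrix proteases and inhibitors 0.50 (0.451) and fibroblast genes 0.47 (0.447). Limma called 0 of 19, 17, 29, 24, 20 and 17 members of these 6 lists. At an unadjusted p under 0.05, 8, 6, 7, 4, 3 and 4 were higher, and 1 macrophage and 1 injury gene were lower. DESeq2 called 1 matrix and 1 fibroblast gene, and adjusted over the list alone limma called 2 injury genes and none of the other 5 lists. Camera did not call the list of T, B and NK lymphocytes (median 0.67, adjusted p = 0.0529) or that of neutrophils (0.42, adjusted p = 0.172). Limma called 0 of their 14 and 3 members, also adjusted over the list alone, with 1 higher in each at an unadjusted p under 0.05 and 0 by DESeq2 or edgeR. Antigen presentation (median 0.35; adjusted p = 0.662 with an estimated correlation), YAP/TAZ targets (0.28; 0.447) and JAK-STAT3 targets (0.44; 0.394) also had 0 called members of 15, 15 and 17. At an unadjusted p under 0.05 these lists had 0, 4 and 3 higher, DESeq2 called 0, and adjusted over the list alone 2 YAP/TAZ targets rose. Cytokines and chemokines had a median of 0.87 (adjusted p = 0.394 with an estimated correlation), with 5 of 23 higher and 1 lower adjusted over the list alone, although the 1 called over all genes, the chemokine gene Cxcl12, fell by 0.61. In the interferon list (median 0.24; adjusted p = 0.583 with an estimated correlation) Ddx58, the RNA sensor RIG-I, rose by 0.45 as 1 of 23. In the p53 and apoptosis list (0.16; 0.447) Eda2r, a death receptor, rose by 1.77 as 1 of 17, with 3 adjusted over the list alone. Many of these lists did not move alike in the 3 Pkd2 knockout mice. KO 3 scored -0.15 for injury, -0.04 for interferon and -0.14 for antigen presentation genes, where KO 1 and 2 had means of 0.71, 0.54 and 0.62. Its fibroblast, matrix protease and complement scores were 18.4, 18.2 and 28.8% of the mean of KO 1 and 2, and its cytokine score 60.0%. The macrophage score was 0.91, 0.85 and 0.13 in KO 1, 2 and 3, and the matrix score of KO 3 was 0.573% of the mean of KO 1 and 2, whereas its G2/M score was 110% of that mean. The JAK-STAT3 scores were 0.54, 0.38 and 0.59 in KO 1, 2 and 3. KO 3 also had the highest erythroid score (2.46) and adipose and adrenal score (1.72) of the 9 mice.

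Several of these calls rested on single libraries. The lymphocyte list was called higher without WT 2, KO 3, DKO 2 or DKO 3 (lowest adjusted p of 0.00411) and without WT 3 and KO 3 together (0.0405). The injury call was lost without WT 1, WT 2, KO 1, KO 2 or DKO 3 (highest adjusted p of 0.270), and the fibroblast call without WT 1, WT 2, KO 1 or KO 2 (0.119). Antigen presentation was lost without WT 3, KO 1 or KO 2 (0.201), YAP/TAZ targets without WT 1, KO 1 or KO 2 (0.104), the interferon list without KO 2 (0.109), matrix proteases without KO 1 (0.0838) and the p53 list without WT 3 (0.0693). Among genes, Cxcl12 was not called without any one WT mouse, KO 1 or KO 2 (highest 0.0995), Ddx58 without any 1 of the 9 mice (0.164) and Eda2r without any one mouse other than KO 3 (0.149). Without KO 3 the p53 list had 3 called members, all higher, and the cytokine list had 1 higher and 1 lower.

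**Figure D2:**
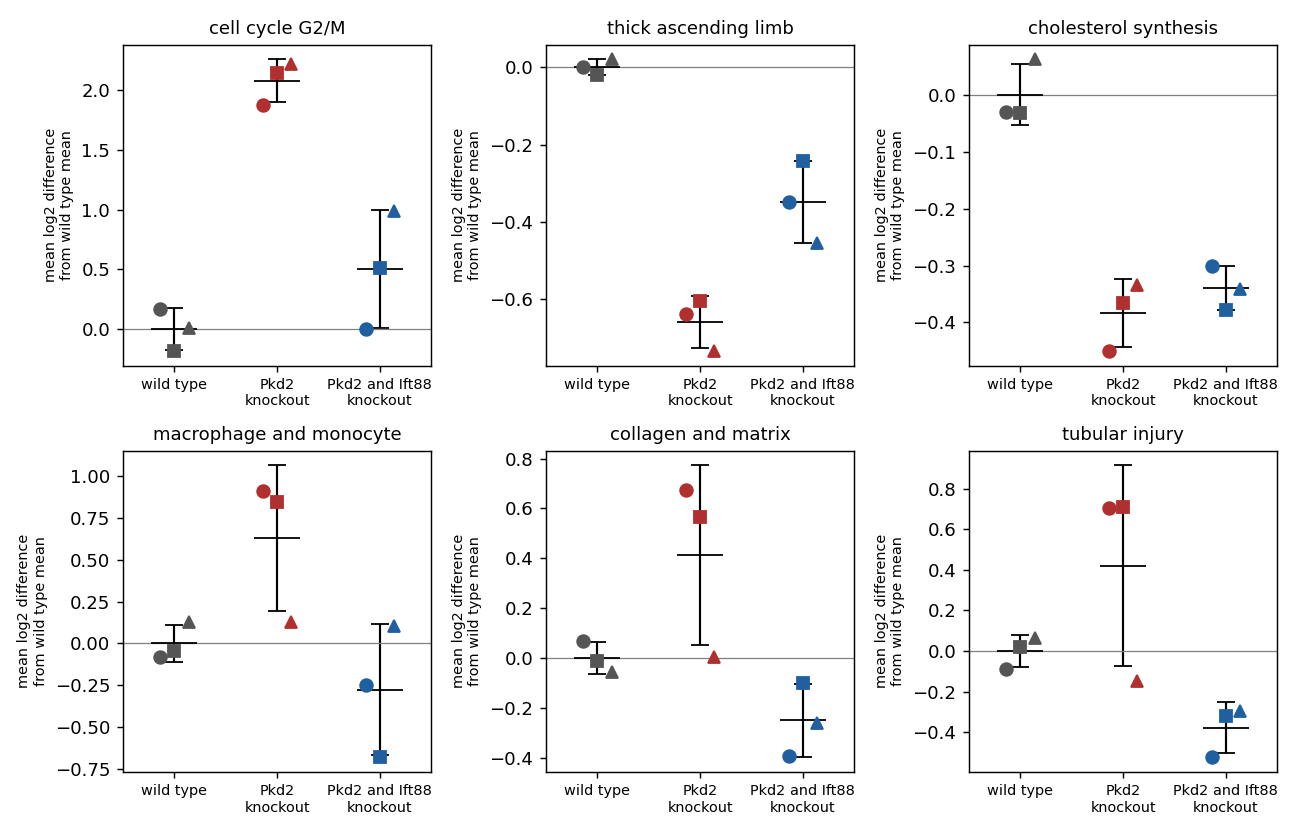
List scores for each mouse, the mean over list members of the log2 difference from the wild type mean, for 6 lists; symbols mark replicates 1 (circle), 2 (square) and 3 (triangle), lines show the mean and SD. The 3 Pkd2 knockout mice lie together for G2/M genes and the thick ascending limb, while replicate 3 lies near wild type for macrophage (0.13), matrix and injury genes.

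Among genes that met the naming rule, which takes a mean of at least 50 and leaves out clone names and pseudogenes, the largest falls in Pkd2 knockout kidneys were in Ugt1a9 and Ugt1a10, encoding glucuronosyltransferases, in the kallikrein Klk1b22 and in the protease inhibitor Spink6. Ugt1a9 was 601 ± 231 normalized counts in wild type and 0.993 ± 1.72 in Pkd2 knockout, and Ugt1a10 was 1124 ± 438 and 31.5 ± 12.1. Klk1b22 was 919 ± 507 and 8.94 ± 6.56, and Spink6 178 ± 70.1 and 0.974 ± 0.994. These 4 were called without any 1 library. Members of the Ugt1a cluster share exons and the Klk1b genes are close paralogs, so the split of reads among them is uncertain. The other Ugt1a members together gained 4249 ± 1326 (SE) while Ugt1a9 and Ugt1a10 lost 1693. Ddit4, a stress-induced inhibitor of mTORC1, fell from 4002 ± 1020 to 634 ± 104 and Gadd45g, a growth arrest gene, from 3607 ± 580 to 773 ± 260. Spns3 fell from 157 ± 27.6 to 34.1 ± 19.2, and Cyp2a4, a steroid hydroxylase with close paralogs, from 25504 ± 5299 to 5730 ± 2643. Ddit4 was not called without WT 1, WT 2, KO 1 or KO 2 (highest adjusted p of 0.0788), Gadd45g without any one WT or KO mouse (0.112), Spns3 without WT 2 or KO 1 (0.0785) and Cyp2a4 without WT 2, KO 1 or KO 2 (0.0624).

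The second comparison asked how kidneys with Pkd2 and Ift88 knocked out together differed from those with Pkd2 knocked out alone. G2/M genes were lower in the double knockout: 8 of 25 members fell, none rose and 17 did not pass, with a median log2 fold change of -1.73. Limma called 62 genes, 20 higher and 42 lower, all with groups that did not overlap, and 15.2% of tested genes had groups that did not overlap (10% by chance). Of the changed genes other than Ift88 that could be placed, 14 of 57 lay on chromosome 14, which also carries Ift88, against 3.44% of tested genes. The call count was 8 without KO 1, 10 without KO 2, 12 without DKO 2, 15 without DKO 1, 28 without WT 2, 35 without WT 1 and 154 without KO 3. edgeR on 7 libraries called 10 genes, none of them in the lists, limma on them 11 and DESeq2 152. The count was 26 with only these 2 groups in the fit, 614 with array quality weights and 308 without WT 3 and KO 3 together. Under quantile normalization 31 genes were called, of which 48.4% were higher, against 32.3% in the main analysis, and with no intensity trend 21.1% of 76 were higher. On 7 libraries the balance turned, with 6 higher and 4 lower by edgeR and 7 higher and 4 lower by limma. Of 22 genes that the naming rule took from these calls, 5 stayed called without any 1 library: Spink6, Gtf2h2, Ppp1r1b, Ogdhl and Ppp1r3e.

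Ccna2, Top2a, Cdk1 and Mki67 fell by 1.54, 1.90, 1.77 and 2.02 on the log2 scale, and Mki67 went from 1104 ± 117 to 291 ± 134 normalized counts. Adjusted over the list alone, 24 of 25 G2/M members fell (camera adjusted p = 1.71e-31; adjusted p = 0.140 with an estimated correlation). In the G1/S list Rrm2 and Uhrf1 fell by 1.44 ± 0.17 and 1.78 ± 0.24, 2 of 20 members, with 12 adjusted over the list alone (camera adjusted p = 1.84e-16; adjusted p = 0.0778 with an estimated correlation). Dtl, a substrate receptor of a replication-linked ubiquitin ligase, Iqgap3 and Ckap2l, both higher in dividing cells, fell by 2.13, 2.02 and 1.96. The G2/M count was 0 without KO 1, KO 2 or DKO 2, 1 without DKO 1, 3 without WT 1 or WT 2, 4 without KO 3 and 15 with DESeq2 on 7 libraries. Without KO 1, KO 2 or DKO 2 the uncalled G2/M members included Ccna2, Top2a, Cdk1 and Mki67. The G1/S count was 0 without KO 1 or KO 2, 1 without any one DKO mouse and 4 without KO 3, and Rrm2 was lost only without KO 1 or KO 2. Dtl was not called without WT 1, WT 2, KO 1, KO 2, DKO 1 or DKO 2 (highest adjusted p of 0.151, as for Mki67 and Cdk1). Iqgap3 was not called without KO 1, KO 2, DKO 1 or DKO 3 (0.137), and Ckap2l without KO 1, KO 2, DKO 1 or DKO 2 (0.126).

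Stromal, macrophage and cytokine lists were lower than in Pkd2 knockout by camera. Col1a1, the collagen I chain, fell from 2201 ± 573 to 523 ± 106 (log2 fold change -2.06 ± 0.29, adjusted p = 0.0335) as the 1 called member of 29 collagen and matrix genes, of which 13 fell adjusted over the list alone (camera adjusted p = 3.86e-11; adjusted p = 0.174 with an estimated correlation). It was also the 1 called of 17 fibroblast genes, where 7 fell adjusted over the list alone (adjusted p = 0.140 with an estimated correlation). Macrophage genes had a median of -0.82 (adjusted p = 0.174 with an estimated correlation), matrix proteases and inhibitors -0.94 (0.140), cytokines and chemokines -1.24 (0.140), tubular injury genes -0.44 (0.223) and complement genes -0.63 (0.174). Limma called 0 of 19, 20, 23, 24 and 17 members of these 5 lists over all genes. Adjusted over the list alone 9, 14, 4, 8 and 2 fell and 1 injury gene rose, at an unadjusted p under 0.05 the lower members were 13, 14, 13, 10 and 6, and DESeq2 called 1, 2, 3, 2 and 1 lower. Antigen presentation (median -0.37; adjusted p = 0.547 with an estimated correlation), interferon (-0.23; 0.547) and p53 genes (-0.12; 0.280) had 0 called by limma, with 0, 2 and 5 lower at an unadjusted p under 0.05, 0 by DESeq2 and 1 p53 gene adjusted over the list alone. Camera did not call the lists of T, B and NK lymphocytes (median -0.39, adjusted p = 0.350) and neutrophils (-0.27, adjusted p = 0.112). Limma called 0 of their 14 and 3 members, with 1 lymphocyte gene higher and 1 neutrophil gene lower at an unadjusted p under 0.05 and adjusted over the list alone, 1 lymphocyte gene higher by DESeq2 and 0 by edgeR. The lymphocyte list was called lower without KO 3 or DKO 3 (lowest adjusted p of 0.00644) and without WT 3 and KO 3 together (0.0471). Clec12a, a lectin of myeloid cells, fell from 97.6 ± 6.87 to 22.7 ± 10.3. Marker lists of blood and fat were also lower, with erythroid genes at a median of -2.65 (adjusted p = 0.280 with an estimated correlation) and adipose and adrenal genes at -0.95 (0.511). KO 3 is the mouse with the highest scores for both, and limma called 0 of 7 members in each, with 6 and 1 lower at an unadjusted p under 0.05, 0 by DESeq2, and 5 and 0 adjusted over the list alone. The adipose and adrenal call was lost without KO 3 or DKO 3 (highest adjusted p of 0.462), antigen presentation without KO 2 or DKO 2 (0.270), interferon without KO 2, DKO 1 or DKO 2 (0.244) and p53 without KO 2 or DKO 1 (0.116). Col1a1 was not called without WT 1, KO 1, KO 2 or any one DKO mouse (highest 0.140), nor Clec12a without any one mouse other than DKO 2 (0.162). Without KO 3 the matrix list had 9 called members and the fibroblast list 2, and without WT 3 each had 2.

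Several lists of nephron genes were higher than in Pkd2 knockout by camera. Thick ascending limb genes had a median log2 fold change of 0.33, with 6 of 13 higher adjusted over the list alone (camera adjusted p = 6.55e-07; adjusted p = 0.140 with an estimated correlation), and Umod, uromodulin, was 91386 ± 18906 and 109420 ± 18651. Intercalated cell genes had a median of 0.32, with 6 of 12 higher adjusted over the list alone (adjusted p = 0.167 with an estimated correlation), and distal convoluted and connecting tubule genes 0.27, with 1 of 11 (adjusted p = 0.174 with an estimated correlation). Limma called 0 members of these 3 lists over all genes, with 7, 6 and 3 higher at an unadjusted p under 0.05, and DESeq2 called 1 intercalated cell gene. The principal cell list was not called (median 0.16, camera adjusted p = 0.0514; adjusted p = 0.547 with an estimated correlation). Limma called 0 of its 12 members, also adjusted over the list alone, with 2 higher at an unadjusted p under 0.05 and 0 by DESeq2 or edgeR, and camera called it without KO 1, KO 2 or DKO 3 (lowest 0.000694). Prodh2 rose from 794 ± 158 to 1943 ± 412 as the 1 called of 24 gluconeogenesis and amino acid genes (median 0.16; adjusted p = 0.204 with an estimated correlation). Camera also called proximal tubule genes (median 0.08; adjusted p = 0.304 with an estimated correlation), podocyte genes (0.13; 0.363), developmental regulators (0.19; 0.167) and xenobiotic genes (0.11; 0.274), each with 0 called members by limma. At an unadjusted p under 0.05 these 4 lists had 7, 2, 3 and 9 higher and 1, 0, 0 and 1 lower. Adjusted over the list alone, 2 proximal tubule and 4 xenobiotic genes were higher and 1 of each was lower. DESeq2 called 1 proximal tubule gene higher, and 1 proximal tubule and 1 xenobiotic gene lower. The xenobiotic list had a mean of -0.18, below 0 where its median and test were above. The distal convoluted tubule call was lost without KO 3 (adjusted p = 0.0574), the developmental call without KO 3 or DKO 1 (highest 0.0904) and the xenobiotic call without KO 2 (0.101). The proximal tubule call was lost without WT 3, KO 2, KO 3, DKO 2 or DKO 3 (0.220) and the podocyte call without WT 1, WT 3, KO 2, KO 3, DKO 1 or DKO 2 (0.270). Quantile normalization also ended the proximal tubule (0.467), podocyte (0.117), xenobiotic (0.0788) and adipose calls (0.0539), and a replicate block ended the podocyte call (0.0599). Leaving out WT 3 and KO 3 together ended the proximal tubule (0.0746), distal convoluted tubule (0.0616), podocyte (0.0830), developmental (0.109) and adipose calls (0.425). Prodh2 was not called without KO 1, KO 2, DKO 1 or DKO 2 (0.126), and its list had 2 called members without KO 3.

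Under the same naming rule, the largest rises were in Spink6, from 0.974 ± 0.994 to 328 ± 130 normalized counts, in Pnp2, a purine nucleoside phosphorylase, from 7.09 ± 4.07 to 125 ± 6.36, and in Rnase4, a ribonuclease, from 476 ± 70.9 to 4661 ± 899. Gtf2h2, a subunit of the transcription factor TFIIH, rose by 1.68 ± 0.07 (adjusted p = 3.57e-05) and Ppp1r1b, the phosphatase inhibitor DARPP-32, by 0.89 ± 0.08. Spns2, a sphingosine-1-phosphate transporter, rose by 0.83 ± 0.13 and Ebpl by 0.91 ± 0.14. The largest falls under that rule were in Ogdhl, an oxoglutarate dehydrogenase-like enzyme, from 194 ± 48.2 to 17.9 ± 4.78, and in Ppp1r3e, a glycogen-targeting phosphatase subunit, from 494 ± 20.6 to 109 ± 18.9. Pnp2, Rnase4, Ebpl, Ogdhl and Ppp1r3e lie on chromosome 14 in GENCODE M21, and Pnp2 has a near-identical neighbour with which it may exchange reads. Pnp2 was not called without WT 2, WT 3, KO 1, KO 2 or any one DKO mouse (highest adjusted p of 0.158), and Rnase4 without WT 2 or any one KO or DKO mouse (0.158). Ebpl was not called without any one mouse other than WT 3 and KO 3 (0.151), nor Spns2 without any one mouse other than KO 3 (0.126).

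**Figure D3:**
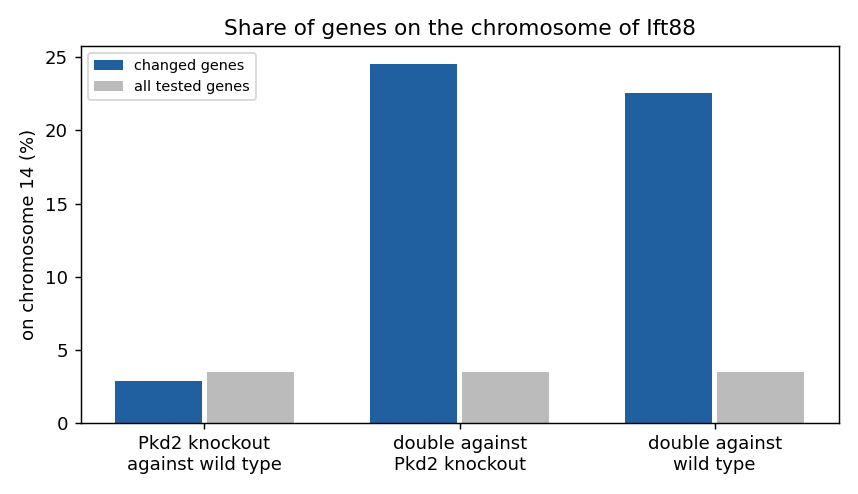
Percent of changed genes (blue) and of all tested genes (grey) that lie on chromosome 14, the chromosome of Ift88, in each of the 3 comparisons, with Ift88 and Pkd2 left out of the changed genes. The share is 24.6% in double against Pkd2 knockout and 22.6% in double knockout against wild type, but 2.83% in Pkd2 knockout against wild type, beside 3.44% of tested genes.

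The third comparison asked how far the double knockout lay from wild type. Limma called 36 genes, of which 12 were higher and 24 lower, all with groups that did not overlap, and 18.3% of tested genes had groups that did not overlap (10% by chance). Of 25 G2/M genes limma called 0, also adjusted over the list alone, with 7 higher at an unadjusted p under 0.05 and 0 by DESeq2 or edgeR. The median was 0.50 and camera called the list (adjusted p = 2.62e-06; adjusted p = 0.834 with an estimated correlation), and Mki67 was 166 ± 31.0 and 291 ± 134. The G2/M scores of DKO 1, 2 and 3 were 0.0042, 0.51 and 0.99, so DKO 1 lay at wild type. Thick ascending limb genes were below wild type as a list, with a median of -0.32 and 8 of 13 lower adjusted over the list alone (camera adjusted p = 2.06e-06; adjusted p = 0.364 with an estimated correlation). Cholesterol synthesis genes had a median of -0.29 with 7 of 18 lower adjusted over the list alone (camera adjusted p = 7.34e-05; adjusted p = 0.276 with an estimated correlation), and Hmgcs1 was 38360 ± 2804 and 21197 ± 4602. Distal convoluted and connecting tubule genes had a median of -0.25 with 4 of 11 lower adjusted over the list alone (adjusted p = 0.431 with an estimated correlation). Over all genes limma called 0 members of these 3 lists, with 9, 7 and 5 lower at an unadjusted p under 0.05 and 0, 1 and 2 by DESeq2. The call count was 18 without WT 1 or without DKO 1, 20 without WT 2 and 58 without WT 3. On 7 libraries edgeR called 10 genes, of which 1 was in a list, lower, in the list of cystic disease genes that holds the deleted Pkd2. Limma on those libraries called 11 and DESeq2 111, and the count was 295 with array quality weights and 111 without WT 3 and KO 3 together.

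Other lists were lower than wild type by camera in the double knockout with 0 members called by limma. Matrix proteases and inhibitors had a median of -0.36 and oxidative phosphorylation genes -0.16, with 1 member of each lower adjusted over the list alone (adjusted p of 0.812 and 0.834 with an estimated correlation). Collagen and matrix genes had a median of -0.33 (adjusted p = 0.834 with an estimated correlation), fibroblast genes -0.34 (0.812), G1/S genes -0.21 (0.812), glycolysis genes -0.15 (0.834) and endothelial genes -0.12 (0.834). At an unadjusted p under 0.05 these 7 lists had 4, 6, 2, 1, 0, 3 and 2 members lower and 1 matrix gene higher, and DESeq2 called 1 matrix protease and 1 oxidative phosphorylation gene. The matrix call was lost without WT 1 or DKO 1 (highest adjusted p of 0.104), the fibroblast call without WT 3 or DKO 2 (0.0657) and the G1/S call without WT 3 or DKO 1 (0.0837). The glycolysis call was lost without WT 3, DKO 1 or DKO 3 (0.167) and the endothelial call without WT 1, WT 2 or DKO 1 (0.239). Leaving out WT 3 and KO 3 together ended the G1/S (0.0953) and glycolysis calls (0.154).

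Genes higher in the double knockout than in wild type included Bcmo1, which cleaves beta-carotene, Agpat9, an acyltransferase of glycerolipid synthesis, and Slco4c1, an organic anion transporter, by 1.11 ± 0.17, 1.06 ± 0.12 and 0.96 ± 0.15 on the log2 scale. Erlin1, an endoplasmic reticulum protein, Cnst, the ETS factor Etv1 and the zinc finger gene Zfp217 rose by 0.79, 0.77, 0.73 and 0.45. Ugt1a9 fell from 601 ± 231 to 1.25 ± 1.37, Ugt1a10 from 1124 ± 438 to 35.9 ± 10.7 and Klk1b22 from 919 ± 507 to 15.1 ± 2.00, with the same uncertainty of read assignment as in Pkd2 knockout. Ogdhl and Ppp1r3e, on chromosome 14, fell by 3.16 ± 0.28 and 1.72 ± 0.18. Tm6sf2, a lipid-handling gene, and Nacad fell by 1.59 and 1.49. Pkd2, Ugt1a9, Ugt1a10, Klk1b22, Ogdhl and Ppp1r3e were called without any 1 library, while Ugt1a9 missed the threshold with a pseudocount of 0.1 (adjusted p = 0.0521). Agpat9 was not called without WT 1 (0.0674), Erlin1 without WT 2 or DKO 1 (highest 0.0588) and Cnst without any one WT mouse, KO 1, KO 2 or DKO 1 (0.199). Bcmo1 and Zfp217 were not called without any one mouse other than KO 3 (0.186 and 0.199), and Slco4c1 without any one mouse other than KO 1 and KO 3 (0.172). Etv1 was not called without any one mouse other than KO 3 and DKO 2 (0.234), Tm6sf2 other than WT 3 and KO 3 (0.182) and Nacad other than KO 3 and DKO 3 (0.165).

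The design also asked how many changes of Pkd2 knockout were moved back in the double knockout. Of the 377 genes changed in Pkd2 knockout, 33 changed in the opposite direction in double against Pkd2 knockout, 27 of them up and then down and 6 down and then up. Among the first were Mki67, Top2a, Cdk1, Ccna2, Ccnb2, Rrm2 and Uhrf1, and among the second Spink6, Prodh2, Ppp1r1b, Spns2 and Gtf2h2. Spink6 was nearly absent in the Pkd2 knockout mice alone (0.974 ± 0.994 normalized counts). Whether a variant of the strain lies behind such genes was not tested. Both comparisons use the same 3 Pkd2 knockout libraries. Unchanged simulated groups gave a mean of 0.02 such genes and at most 1 in 100 draws, and independent lists would share 0.731. The draws hold no effect of Pkd2, so few genes can be called in them and a low count was given in advance. They do not show how many genes would seem moved back if Ift88 loss changed nothing. Across genes, which are not independent replicates, the changes correlated at -0.68, against a simulated -0.50, with a covariance of -0.146 against a simulated -0.0394. No split of 3 libraries keeps 2 in each part, so part of the excess may come from the shared libraries. The 180 genes higher in Pkd2 knockout had a median log2 difference from wild type of 1.14 there and 0.33 in the double knockout, and the 197 lower ones -0.78 and -0.41. Genes chosen for a large difference in one group lie nearer to wild type in another by selection alone. The moved-back count was 3 without KO 1, 5 without KO 2, 83 without KO 3, 7 without DKO 2, 8 without DKO 1, 15 without WT 2 and 21 without WT 1. It was 51 with a pseudocount of 10, 12 under quantile normalization, 8 with only the groups compared, 441 with array quality weights and 117 without WT 3 and KO 3 together. On 7 libraries it was 2 with edgeR or limma and 74 with DESeq2. For the changes of both mutant groups against the shared wild type libraries, the changes correlated at 0.48, against a simulated 0.50 (0.44 to 0.57), and the covariance was 0.0852 (simulated 0.0392). In both mutant groups 22 genes were called in the same direction, 6 higher and 16 lower, where simulation gave a mean of 0.01 and independent lists would share 0.137 and 0.300. The simulated mean is again low by construction, because the draws hold no effect of genotype.

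**Figure D4:**
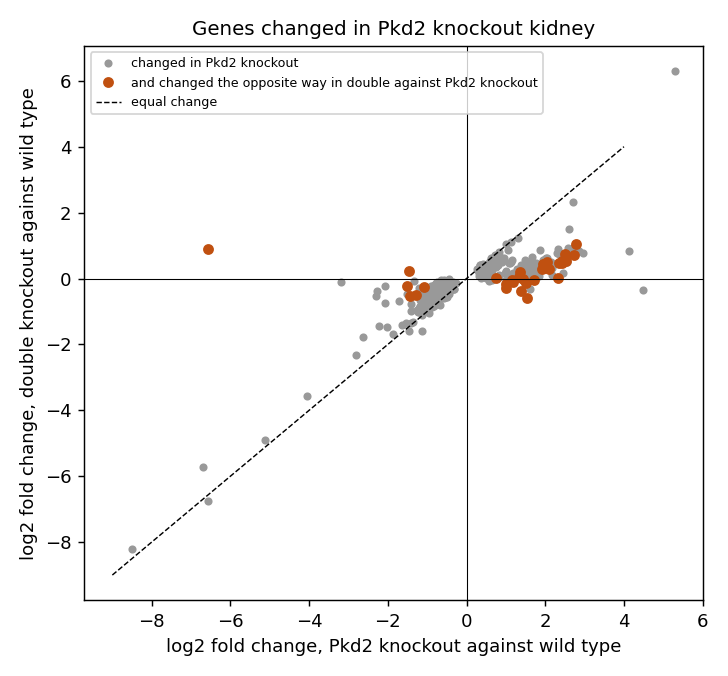
Log2 fold change against wild type in Pkd2 knockout (horizontal) and double knockout (vertical) for the 377 genes changed in Pkd2 knockout; orange points are the 33 that changed the opposite way in double against Pkd2 knockout, and the dashed line marks equal change. Most genes higher in Pkd2 knockout lie below the line, 156 of 180 between wild type and Pkd2 knockout, and Spink6 lies apart at -6.56 and 0.89.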

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

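The fit without WT replicate 3 and Pkd2 knockout replicate 3 and the limma fit to the same 7 libraries were chosen after seeing the data. The list tests without each library were not planned either. Order of counts: Pkd2 knockout against wild type, double against Pkd2 knockout, double knockout against wild type, and genes moved back (377, 62, 36 and 33 in the main analysis). Leaving out one library gave 70 to 436, 8 to 154, 18 to 58 and 3 to 83. Array quality weights gave 3222, 614, 295 and 441. With only the 2 groups compared, the second count was 26 and the fourth 8. Quantile normalization gave 31 and 12 for these, and a pseudocount of 10 gave 51 moved back. A log2 fold of at least 1 left 161 genes in the first comparison, by construction. edgeR on 7 libraries gave 11, 10, 10 and 2, and limma on the same libraries 13, 11, 11 and 2; DESeq2 on them gave 296, 152, 111 and 74, with more false calls in simulation. Without WT replicate 3 and Pkd2 knockout replicate 3, which also leaves 7 libraries, the counts were 517, 308, 111 and 117. Median-ratio scaling moved nothing, which was given in advance if DESeq2 had already scaled the deposited values in that way. No scaling shifted the median of all genes by over 0.1 on the log2 scale. The 7 libraries with recovered reads lack replicate 1 of wild type and Pkd2 knockout, which leaves mice of different name prefixes in these groups. Leaving out replicate 3 of both leaves mice of the same prefix, so the number of libraries alone does not set the count. In the first comparison 293 and 397 genes were called without replicate 3 of wild type or of Pkd2 knockout. Without replicate 1 or 2 of either group 70 to 106 were called. Why was not tested, nor was any cause other than those named.

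Same-numbered mice did not deviate together (correlations of -0.14 to 0.21), so the numbers do not pair them; with a replicate block the counts were 217, 15, 20 and 8. Camera called 23, 22 and 11 of the 43 lists; an estimated correlation left 0, 0 and 0, fry called 5, 8 and 2, and fry with the replicate block 6, 3 and 2. No called result reversed its direction under any alternative. Of 78 calls of named genes, 26 stayed called without any 1 library and 52 did not. Limma recovered 83% of the 2-fold changes simulated for the first comparison, with independent mice and genes with a mean of at least 50. On 7 libraries the simulated calls went from 189 to 179, whereas the real ones went from 377 to 13. The simulation therefore does not give the power of the real data.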

Other observations

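The tests of a segment linked to Ift88, of the Ugt1a genes and of Klk1b22 taken alone, of depth, of Pkd2 knockout replicate 3 and of the splits were chosen only after the result was seen. Gene lists not described above changed in few members. By limma the list named intraflagellar transport and ciliary core had 0 of 33 members changed by loss of Pkd2, with 2 lower at an unadjusted p under 0.05 and 0 by edgeR or DESeq2. In double against Pkd2 knockout 1 member changed, Ift88 itself. In other lists the following passed in Pkd2 knockout against wild type and were named after their values were seen. Wnt11, a Wnt ligand of kidney development, fell by 2.81 ± 0.38 (log2, SE), Sfrp1, a secreted Wnt antagonist, by 0.81 and Cldn8, a claudin of the distal nephron, by 0.75. Slc5a12, a lactate transporter of the proximal tubule, rose by 1.04 ± 0.18, the platelet-derived growth factor gene Pdgfb by 0.69 and Glis2, a gene of cystic disease, by 0.45. Miox, myo-inositol oxygenase, fell by 0.66 ± 0.09 and Cyp7b1, a male-biased enzyme, by 0.98. Leaving out 1 library ended several of these calls. The developmental list, with Wnt11, had 0 members called without WT 2 and 1 each way without KO 3, the Wnt list, with Sfrp1, 0 without WT 1, and the male-biased list, with Cyp7b1, 0 without WT 1 or KO 1 and 1 each way without KO 3. The proximal tubule list had 0 called higher without WT 1, WT 2, KO 1 or KO 2, and 0 called lower without WT 2. The growth factor list had 0 called higher without WT 1, WT 2, KO 1 or KO 2, and the claudin list had 2 called lower without DKO 2 or DKO 3. The cystic disease list had 1 called, lower, without WT 1, WT 2 or KO 2. This is the deleted gene Pkd2, which is a member and was called without any 1 library.

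Hedgehog, TGF-beta, unfolded protein, cAMP and fatty acid oxidation lists had 0 members called by limma in any comparison. At an unadjusted p under 0.05 they had 1, 2, 1, 3 and 6 members in Pkd2 knockout against wild type, 1, 5, 1, 3 and 1 in double against Pkd2 knockout, and 0, 2, 1, 0 and 5 in double knockout against wild type. edgeR called 0 of them, and DESeq2 called 1 TGF-beta target lower in each comparison with the double knockout. Some lists that camera did not call had a median, mean and test that differed in sign. These were claudins, cAMP and male-biased genes in Pkd2 knockout against wild type, and Wnt and unfolded protein genes in double against Pkd2 knockout. In double knockout against wild type they were proximal tubule, complement, fatty acid oxidation, growth factor, xenobiotic, cystic disease, cAMP, developmental and ciliary genes.

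Changed genes in the double knockout gathered on the chromosome of Ift88. Without Ift88, 14 of the 57 placed genes changed against Pkd2 knockout lie on chromosome 14, where 10000 circular shifts of the calls gave a median of 1 and a 95th percentile of 5 (permutation p = 0.0154; adjusted p = 0.0687 over the 6 such tests, so it does not pass that adjustment). Structure of the chromosome alone is argued against by Pkd2 knockout against wild type, where 10 of 353 genes lie there (shift median 12, 95th percentile 18), and paralogous neighbours by the 7 of 31 left after removing, on every chromosome, genes that share leading letters with another tested gene of their own chromosome (95th percentile 3). A candidate explanation is a segment inherited with the floxed Ift88 allele, which may differ in sequence from C57BL/6, but effects of the deletion on its neighbours were not tested. For Pkd2 on chromosome 5, 23 of 353 changed genes (median 21, 95th percentile 29) leave a linked segment undecided. In double knockout against wild type 0 of 31 placed genes lie on chromosome 5, where the shifts gave a median of 1 and a 95th percentile of 7. With so low a median that count does not decide it either.

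Ugt1a9, Ugt1a10 and Klk1b22 lost nearly all reads in both mutant groups. Lower depth is argued against by the recovered reads of 7 libraries, where the lower mutant group mean was 113% of the wild type mean. Reads assigned to other family members may account for the Ugt1a part, since the other members gained 251% of the reads lost in Pkd2 knockout and 307% in the double knockout, more than a transfer alone would give. The test written for both families as one was undecided (-114% in Pkd2 knockout and 393% in the double knockout), as was Klk1b22 alone (-792% and 554%), each with an SE larger than the loss. The Klk1 family was taken as the 8 tested genes whose symbol begins with Klk1, a wider pattern than the Klk1b paralogs. Its other members changed by -7207 ± 6470 (SE) in Pkd2 knockout beside a loss of 910, so this test could not decide. A variant of the strain stays open.

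Pkd2 knockout replicate 3 lay near wild type for macrophage, matrix and injury genes. A wild type or undeleted mouse is argued against by its Pkd2 level, 39.4% of wild type, and dilution by blood or fat by its G2/M score, 110% of the mean of replicates 1 and 2. Pkd2 does not separate it from a double knockout, but its Ift88 count of 1214 lies above the 691 to 831 of those mice. A different breeding line may be involved, judged by squared differences between mice relative to sampling noise. In wild type and Pkd2 knockout, pairs with different name prefixes had a ratio of at least 16.1 and pairs with the same prefix at most 4.42. Double knockout mice share a prefix, which replicate 3 writes with a hyphen. Their ratio was 8.84 for replicates 1 and 2, and 14.6 and 12.7 for the pairs of replicates 1 and 2 with replicate 3. Wild type and Pkd2 knockout have only 1 mouse each of the other prefix, so line and single mouse cannot be told apart. Individual differences in disease between mice stay open, as untested.

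The 10 splits of each 6 samples are too few for a share under 0.05 (the smallest is 0.1). In each comparison 1 split, the real one, gave as many genes: 377, 62 and 36, with 1, 1 and 4 as the highest of the other splits.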
